A study of Mus musculus with 24 samples.

How the data were processed

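Poly(A)-selected RNA was sequenced from cultured mouse ovarian surface epithelial (mOSE) cells, the single layer that covers the ovary. The 24 libraries form 8 groups of 3 and belong to 3 experiments. In the first, 12 libraries of the line m1102 were grown as attached monolayers or as spheroids in low-attachment culture, each with or without TGFB1, the cytokine transforming growth factor beta 1. TGFB1 was given at 10 ng/mL, for spheroids over 4 days before low-attachment culture. The titles mark all 6 monolayer libraries, and no spheroid library, as re-analysed, which points to earlier data, so culture and origin of the libraries cannot be separated. In the second, 6 libraries of the same line carried a lentiviral vector with Snail (the product of Snai1) or the empty WPI vector. In the third, 6 libraries of a line with floxed Brca1 alleles received adenoviral Cre, which deletes the floxed part of the gene, or adenoviral GFP as the control. Nothing in the labels says whether the 3 libraries of a group are separate cultures, so the p-values measure only the spread between these libraries. The labels of untreated monolayers 1 and 2 cite the same earlier sample, yet their values differ (r = 0.991), so whether they are 2 replicates is open.

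The submitters' processing notes name kallisto 0.44.0 and sleuth 0.30.0 on the mouse build GRCm38. The authors deposited 1 table of signal values per experiment, named as TPM and given per gene. The columns sum to between 796668 and 1810667 rather than to 1000000, so the deposited signal is treated as TPM scaled by the authors with a factor per library, and is called scaled TPM here. The 3 tables were normalized separately and levels are not compared between them. The authors' result tables hold a deposited p-value and q-value per gene and coefficients on the natural log scale, which were divided by the natural log of 2 for comparison with log2 values. In the monolayer and spheroid table the deposited p-value covers 3 terms at once. Reads and counts were not used here, so the depth of each library is unknown and no counting interval is given. The deposited gene identifiers were matched to GENCODE M21, also on GRCm38, with 98.1% to 98.2% found.

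Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) on log2(scaled TPM + 1). Genes with a scaled TPM of at least 1 in at least 3 libraries of the table were tested: 13509 in the monolayer and spheroid table, 12240 in the Snail table and 12775 in the BRCA1 table. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the tables. The 12 monolayer and spheroid libraries were fitted together with a mean per group, and the interaction was tested as the TGFB1 effect in spheroids minus that in monolayers. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. Values after ± are standard errors for log2 fold changes and SD for scaled TPM, with n = 3 libraries per group. The test had been planned for plain TPM and was kept for scaled TPM, since a factor per library leaves the type of value the same. On simulated data with the groups and spread of each experiment, the test recovered 88% to 95% of 2-fold changes in the monolayer and spheroid comparisons, 70% for the interaction, 100.0% for Snail and 2% for BRCA1, where 65% of 4-fold changes were recovered. False calls were 2.09% to 9.39% of the simulated calls. Changes were put into 100 genes of each size, none of low level, with independent noise of equal spread in all libraries. The real libraries were not equally alike, least so the BRCA1 controls, and most comparisons called many more genes. These shares therefore need not hold for the real data or for low genes.

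Before the data were examined, 30 gene lists, the test, the rule for named genes and most alternatives were fixed. The lists were epithelial junction and keratin genes, ovarian surface and mesothelial genes, EMT transcription factors, mesenchymal and matrix genes, TGF-beta and SMAD target genes, actin and SRF target genes, YAP and TEAD target genes, stemness genes, WNT target genes, NOTCH pathway genes, mitosis genes, DNA replication genes, p53 target genes, homologous recombination and damage checkpoint genes, hypoxia response genes, glycolysis genes, cholesterol synthesis genes, NF-kB and inflammatory genes, interferon response genes, integrated stress response genes, ER chaperone genes, immediate early genes, antioxidant NRF2 target genes, leukocyte markers, endothelial markers, granulosa and theca markers, ovarian stroma and fibroblast markers, oviductal epithelium markers, oocyte markers and mitochondrially encoded protein genes. Lists with at least 5 tested genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera compares a list with all other genes for a shift in 1 direction, so members that move opposite ways can cancel. With an estimated correlation, its p-value also rests on the residual degrees of freedom alone. These were 8 in the monolayer and spheroid fit and 4 in the Snail and BRCA1 fits. A list can therefore miss the threshold in that form without strongly correlated members. Members were counted over all genes tested and adjusted over the list alone. Leukocyte, endothelial and oocyte markers had fewer than 5 tested genes and are given as levels. The rule named Snai1, Brca1, Tgfb1, Ly6a and Ptgs2 in every comparison. It added up to 8 called genes per direction with the largest change, of which 1 group had a mean of at least 5 scaled TPM. Predicted and clone-based gene symbols were left out. Except for the interaction, the 2 groups of such a gene also had to be without overlap. It also added up to 4 called members per list that passed or had at least 50% of its members called, and the highest marker of each other cell type. Sets of 200 genes per direction from 1 comparison were tested in comparisons that share no library with it (24 tests).

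Alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter, a filter at 5, quantile normalization, upper quartile scaling, a replicate block, no variance trend, only the 6 libraries compared, and each library left out in turn. Added after seeing the data were scaling each library to a sum of 1000000, BRCA1 without controls 1 and 3, and limma library quality weights. A planned transcript-level test does not apply to gene-level tables. The labels do not say that replicate numbers pair the libraries, so no block was used. Comparisons that share a group were not tested for a shared signature.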

Results

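The data are gene expression levels of 24 libraries from mouse ovarian surface epithelial cells, in scaled TPM, 3 libraries per group. Summed signal per library was 955433 to 1166749 in the monolayer and spheroid table, 983449 to 1021026 in the Snail table and 796668 to 1810667 in the BRCA1 table. The series asks for a transcriptional profile of stemness in this epithelium, under spheroid culture, TGFB1, Snail and loss of BRCA1. The genes followed in every comparison are protein-coding and lie on GRCm38: Snai1 (ENSMUSG00000042821) on chromosome 2, 167538195 to 167542814; Brca1 (ENSMUSG00000017146) on chromosome 11, 101488764 to 101551955; Tgfb1 (ENSMUSG00000002603) on chromosome 7, 25687002 to 25705077; Ly6a (ENSMUSG00000075602) on chromosome 15, 74994877 to 74998031; and Ptgs2 (ENSMUSG00000032487) on chromosome 1, 150100031 to 150108227. Snai1 encodes a repressor of epithelial genes, Brca1 a homologous recombination factor, Ly6a the surface antigen Sca-1 and Ptgs2 cyclooxygenase 2.

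The first comparison asks what spheroid culture changes in untreated cells. The mitosis and DNA replication lists fell and the hypoxia, glycolysis and inflammatory lists rose at the preset correlation, but none passed with an estimated correlation (adjusted p = 0.0528 to 0.381). Ccnb1, the mitotic cyclin B1, fell from 63.8 ± 11.2 to 1.56 ± 0.337 scaled TPM (log2 fold change -4.65 ± 0.19, adjusted p = 3.08e-08). Ptgs2 rose from 110.0 ± 6.90 to 732 ± 239 (log2 fold change 2.66 ± 0.31, adjusted p = 3.49e-05), and Krt7, a simple-epithelium keratin, fell from 329 ± 37.8 to 2.69 ± 0.74 (log2 fold change -6.50 ± 0.21, adjusted p = 1.3e-08). Snai1 rose from 1.16 ± 0.225 to 4.26 ± 2.04 (adjusted p = 0.0067), Tgfb1 rose (1.42 ± 0.13 log2) and Brca1 fell (-2.07 ± 0.15 log2). Ly6a was 1.68 ± 0.759 in monolayers and 1.62 ± 0.427 in spheroids and did not pass the test (adjusted p = 0.985).

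In all, 7461 of 13509 genes were called, 3725 higher and 3736 lower in spheroids, 2554 of them by at least 2-fold. The titles mark all monolayer libraries, and no spheroid library, as re-analysed, so a difference in batch cannot be told from one of culture. The 2 groups did not overlap in 65.3% of genes, against 10% by chance. Among the largest increases, with all 3 spheroid libraries above all 3 monolayer libraries as the rule required, were Sprr1a (8.57 ± 1.496), Akr1cl (8.11 ± 0.89), Col15a1 (7.70 ± 0.47) and Olfm1 (7.32 ± 0.26). Sprr1a encodes a cornified envelope precursor and Col15a1 a basement membrane collagen. Among the largest decreases were Prph (-6.88 ± 0.50), Tagln (-6.82 ± 0.31), Acta2 (-6.35 ± 0.52), Upk1b (-5.84 ± 0.61) and Upk3b (-5.76 ± 0.37). Tagln and Acta2 encode smooth-muscle cytoskeletal proteins, and Upk1b and Upk3b uroplakins expressed in mesothelium.

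Of the fixed lists, mitosis genes fell as a group: 0 rose and 24 fell of 24 tested (0 and 24 adjusted over the list alone), median log2 fold change -3.80, adjusted p = 6.62e-20, and adjusted p = 0.18 with an estimated correlation. DNA replication genes fell too: 0 rose and 27 fell of 27 tested (0 and 27 adjusted over the list alone), median log2 fold change -1.46, adjusted p = 2.24e-12, and adjusted p = 0.181 with an estimated correlation. Members included Rrm2 (-3.10 ± 0.22) and Mcm5 (-2.72 ± 0.19). Homologous recombination and damage checkpoint genes followed: 1 rose and 20 fell of 26 tested (1 and 21 adjusted over the list alone), median log2 fold change -0.996, adjusted p = 2.87e-06, and adjusted p = 0.197 with an estimated correlation. Members included Exo1 (-3.45 ± 0.20). For actin and SRF target genes, 0 rose and 15 fell of 17 tested (0 and 15 adjusted over the list alone), median log2 fold change -1.10, adjusted p = 2.87e-06, and adjusted p = 0.197 with an estimated correlation. Ovarian surface and mesothelial genes fell: 2 rose and 11 fell of 16 tested (2 and 12 adjusted over the list alone), median log2 fold change -1.85, adjusted p = 0.00124, and adjusted p = 0.25 with an estimated correlation, although Igfbp5, an IGF binding protein, rose (5.95 ± 0.62). Among epithelial junction and keratin genes, 1 rose and 9 fell of 15 tested (1 and 9 adjusted over the list alone), median log2 fold change -0.71, adjusted p = 0.0186, and adjusted p = 0.181 with an estimated correlation. Members included Cdh3 (-3.64 ± 0.32) and Esrp2 (-2.94 ± 0.15). That last call ended with no filter on low values (adjusted p = 0.0508).

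Hypoxia response genes rose: 17 rose and 1 fell of 19 tested (17 and 1 adjusted over the list alone), median log2 fold change 1.40, adjusted p = 2.87e-06, and adjusted p = 0.0528 with an estimated correlation. Ero1l, a thiol oxidase, rose from 63.4 ± 5.09 to 943 ± 351, and the glucose transporter gene Slc2a1 from 18.9 ± 1.99 to 120.2 ± 12.2. Glycolysis genes rose: 15 rose and 0 fell of 17 tested (15 and 0 adjusted over the list alone), median log2 fold change 1.02, adjusted p = 4.13e-06, and adjusted p = 0.181 with an estimated correlation. Members included Hk1 (3.69 ± 0.21) and Pfkl (1.83 ± 0.16). In the immediate early list, 13 rose and 1 fell of 16 tested (13 and 1 adjusted over the list alone), median log2 fold change 1.01, adjusted p = 0.000216, and adjusted p = 0.18 with an estimated correlation. Members included Ier3 (2.86 ± 0.32) and Fosb (2.77 ± 0.47). Cholesterol synthesis genes rose: 12 rose and 0 fell of 22 tested (16 and 1 adjusted over the list alone), median log2 fold change 0.93, adjusted p = 0.000616, and adjusted p = 0.516 with an estimated correlation. NF-kB and inflammatory genes rose: 13 rose and 2 fell of 22 tested (13 and 2 adjusted over the list alone), median log2 fold change 1.41, adjusted p = 0.00147, and adjusted p = 0.381 with an estimated correlation, with the chemokines Ccl7 (3.47 ± 0.34) and Ccl2 (3.14 ± 0.34). Markers of granulosa and theca cells, the hormone-producing cells of the follicle, rose: 6 rose and 0 fell of 6 tested (6 and 0 adjusted over the list alone), median log2 fold change 1.807, adjusted p = 0.00249, and adjusted p = 0.181 with an estimated correlation. Cyp11a1, which makes pregnenolone from cholesterol, rose from 0.297 ± 0.0148 to 113 ± 67.1 and Star, a mitochondrial cholesterol carrier, from 293 ± 22.8 to 1632 ± 545.

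Stemness genes did not pass as a list: 6 rose and 1 fell of 14 tested (6 and 1 adjusted over the list alone), median log2 fold change 0.37, adjusted p = 0.0679, and adjusted p = 0.307 with an estimated correlation. Within it, Cd44 (2.91 ± 0.47) and Myc (1.93 ± 0.40) rose. EMT transcription factors did not pass: 6 rose and 1 fell of 8 tested (6 and 1 adjusted over the list alone), median log2 fold change 0.75, adjusted p = 0.0624, and adjusted p = 0.181 with an estimated correlation. Of these, Zeb1 (1.73 ± 0.12) and Zeb2 (1.13 ± 0.14) rose. The other lists that missed the threshold were TGF-beta and SMAD targets (median -0.17), NOTCH pathway genes (0.53), p53 targets (-0.23), interferon response genes (-0.34), integrated stress response genes (0.30), ER chaperones (-0.08), mitochondrially encoded genes (0.01), WNT targets (-0.41), antioxidant NRF2 targets (0.33), ovarian stroma and fibroblast markers (0.26), mesenchymal and matrix genes (-0.86), YAP and TEAD targets (-0.68) and oviductal epithelium markers (median 0.39, mean and test negative). A missed threshold does not show that members stayed unchanged, since opposite moves can cancel. The authors' log2 coefficients for spheroid culture were 7.10 for Tgfbi and -5.66 for Id3, both TGF-beta and SMAD targets. They were 4.58 for Tnc and -5.26 for Fbln5, both in the mesenchymal and matrix list. Of the 113 called genes that the rule named, 110 kept their call in each fit without 1 library and 111 in all other settings.

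**Figure D1:**
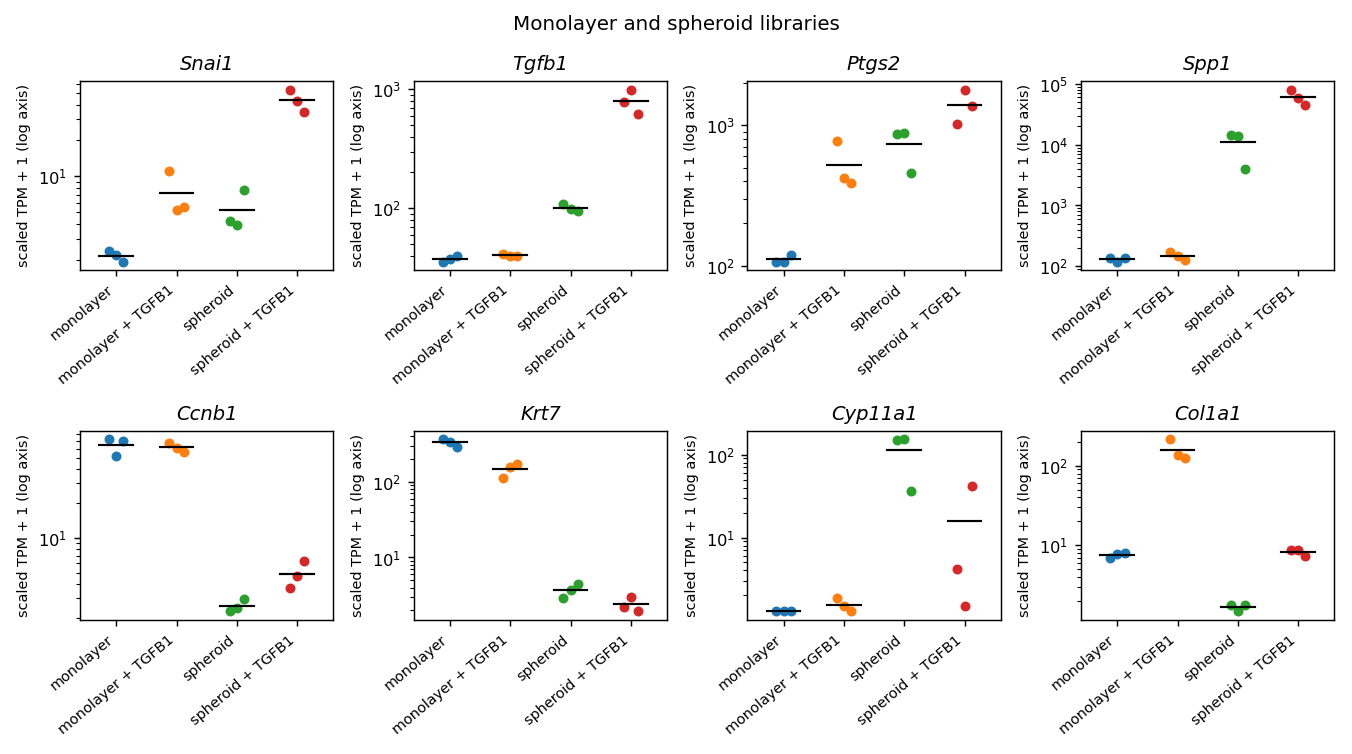
Scaled TPM + 1 on a log axis of 8 genes in the monolayer and spheroid table, with a point per library and a line at the mean of the 3 libraries of a group. Ccnb1 and Krt7 lie lower in both spheroid groups than in both monolayer groups, while Spp1 lies higher. The means of Ptgs2 are also higher in spheroids. For Ptgs2, however, TGFB1 monolayers and untreated spheroids are close relative to their SD, and that pair was not tested.

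The next comparison asks what TGFB1 changes in monolayers. Col1a1, a fibrillar collagen gene, rose from 6.59 ± 0.517 to 157 ± 49.2 scaled TPM (log2 fold change 4.34 ± 0.18, adjusted p = 7.82e-07), and Lox, which cross-links collagen, from 159 ± 17.8 to 1270.1 ± 408 (2.95 ± 0.27). Snai1 rose from 1.16 ± 0.225 to 6.25 ± 3.26 (log2 fold change 1.66 ± 0.31, adjusted p = 0.00542) and Ptgs2 from 110.0 ± 6.90 to 523 ± 209.8 (log2 fold change 2.17 ± 0.31, adjusted p = 0.00125). Tgfb1 and Brca1 did not pass (adjusted p = 0.665 and 0.575).

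Other large increases were Crispld2 (4.56 ± 0.35), S1pr1 (4.45 ± 0.20), Ctla2a (4.44 ± 0.31), Wnt7b (3.80 ± 0.40) and Igf1 (3.61 ± 0.29), and large decreases Cyp2s1 (-3.59 ± 0.53), Akr1c18 (-3.45 ± 0.72), Cyp2f2 (-3.42 ± 0.32), Slpi (-3.31 ± 0.43) and Ugt1a7c (-2.80 ± 0.44). Cyp2s1 and Cyp2f2 are cytochromes P450 and Slpi is a protease inhibitor. In each of these genes the 3 treated libraries lay outside the range of the 3 untreated ones, which the rule for the largest changes required. Mesenchymal and matrix genes rose as a list: 15 rose and 3 fell of 29 tested (19 and 3 adjusted over the list alone), median log2 fold change 0.81, adjusted p = 2.46e-07, and adjusted p = 0.278 with an estimated correlation. TGF-beta and SMAD targets rose: 8 rose and 0 fell of 23 tested (8 and 0 adjusted over the list alone), median log2 fold change 0.35, adjusted p = 0.014, and adjusted p = 0.313 with an estimated correlation. Members included Nuak1 (2.40 ± 0.18) and Pmepa1 (1.75 ± 0.23). ER chaperone genes rose: 13 rose and 0 fell of 18 tested (15 and 0 adjusted over the list alone), median log2 fold change 0.47, adjusted p = 1.44e-07, and adjusted p = 0.313 with an estimated correlation. Members included Hyou1 (0.97 ± 0.14) and Hsp90b1 (0.71 ± 0.11). For actin and SRF targets, 9 rose and 0 fell of 17 tested (10 and 0 adjusted over the list alone), median log2 fold change 0.51, adjusted p = 0.000281, and adjusted p = 0.551 with an estimated correlation. Members included Cnn1 (1.55 ± 0.31) and Actn1 (0.93 ± 0.16). Ovarian surface and mesothelial genes fell: 1 rose and 4 fell of 16 tested (1 and 4 adjusted over the list alone), median log2 fold change -0.51, adjusted p = 0.0381, and adjusted p = 0.706 with an estimated correlation. Members included Gpm6a (-2.25 ± 0.45) and C3 (-2.68 ± 0.55) lower and Cd200 (2.81 ± 0.26) higher.

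That last list was no longer called without untreated monolayer 1 (adjusted p = 0.0651) or TGFB1 monolayer 1 (adjusted p = 0.0811), or with library quality weights (adjusted p = 0.0685). Ly6a fell from 1.68 ± 0.759 to 0.425 ± 0.403 (adjusted p = 0.0488), a call lost without untreated monolayer 2 (adjusted p = 0.129), untreated monolayer 3 (adjusted p = 0.177), TGFB1 monolayer 1 (adjusted p = 0.181) or TGFB1 monolayer 2 (adjusted p = 0.0936). Medians, means and tests differed in sign for epithelial junction and keratin genes, stemness genes, WNT target genes, hypoxia response genes and granulosa and theca markers, none of which passed. In all, 2284 genes were called, 1232 higher and 1052 lower, 579 of them by at least 2-fold, and groups did not overlap in 47.5% of genes (10% by chance). The count was 1274 without untreated monolayer 1, 1330 without untreated monolayer 2, 1220 without untreated monolayer 3 and 1261 without TGFB1 monolayer 1, with 3771 in a fit of only the 6 libraries compared and 6431 with library quality weights. Of the 42 called genes that the rule named, 36 kept their call in each fit without 1 library and 38 in all other settings.

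TGFB1 was also compared with no treatment in spheroids. Timp1, a metalloproteinase inhibitor, rose from 271 ± 121 to 11284 ± 1284 scaled TPM (log2 fold change 5.45 ± 0.28, adjusted p = 3.99e-07). Fn1, which encodes fibronectin, rose from 415 ± 88.2 to 6889.7 ± 2110.2 (log2 fold change 4.02 ± 0.22, adjusted p = 6.14e-07). Tgfb1 itself rose from 99.8 ± 6.96 to 797 ± 185 (log2 fold change 2.96 ± 0.13, adjusted p = 1.69e-07) and Snai1 from 4.26 ± 2.04 to 42.6 ± 9.41 (log2 fold change 3.09 ± 0.31, adjusted p = 5.6e-05). Cyp11a1 fell from 113 ± 67.1 to 14.9 ± 22.7 and Star from 1632 ± 545 to 569 ± 159. Cyp11a1 was not called in a fit of only the 6 libraries compared (adjusted p = 0.068).

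Large increases were Col5a3 (7.16 ± 0.27), Vsig8 (7.04 ± 0.33), S100a8 (6.47 ± 1.05) and Cotl1 (6.07 ± 0.39), and large decreases Kctd14 (-5.36 ± 1.07), Clec2h (-4.61 ± 0.91), Serpinb1a (-4.15 ± 0.63), Amhr2 (-4.06 ± 0.66) and Dpt (-3.76 ± 0.71). Amhr2 encodes the receptor of anti-Müllerian hormone. In each of them the 3 treated libraries lay outside the range of the untreated ones, which the rule for the largest changes required. Cholesterol synthesis genes fell: 0 rose and 18 fell of 22 tested (0 and 19 adjusted over the list alone), median log2 fold change -1.23, adjusted p = 1.58e-06, and adjusted p = 0.599 with an estimated correlation. Members included Insig1 (-1.73 ± 0.40) and Hmgcs1 (-1.62 ± 0.30). Glycolysis genes fell: 1 rose and 12 fell of 17 tested (1 and 12 adjusted over the list alone), median log2 fold change -0.72, adjusted p = 0.000498, and adjusted p = 0.564 with an estimated correlation. Members included Gpi1 (-1.36 ± 0.21) and Pfkl (-1.08 ± 0.16). Granulosa and theca markers fell: 0 rose and 5 fell of 6 tested (1 and 5 adjusted over the list alone), median log2 fold change -1.73, adjusted p = 0.00824, and adjusted p = 0.45 with an estimated correlation. In the interferon response list, 1 rose and 9 fell of 22 tested (1 and 9 adjusted over the list alone), median log2 fold change -0.38, adjusted p = 0.0048, and adjusted p = 0.645 with an estimated correlation, with Ifi27l2a lowest (-2.78 ± 0.40). Ovarian surface and mesothelial genes fell: 1 rose and 8 fell of 16 tested (1 and 8 adjusted over the list alone), median log2 fold change -0.47, adjusted p = 0.00926, and adjusted p = 0.599 with an estimated correlation. Members included Nkain4 (-2.18 ± 0.41) and Lrrn4 (-1.83 ± 0.28). This call ended with scaling to equal sums (adjusted p = 0.072).

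TGF-beta and SMAD targets rose: 13 rose and 1 fell of 23 tested (16 and 1 adjusted over the list alone), median log2 fold change 0.65, adjusted p = 8.91e-05, and adjusted p = 0.26 with an estimated correlation. Members included Inhba (4.82 ± 0.63) and Pmepa1 (3.46 ± 0.23). Mesenchymal and matrix genes rose: 16 rose and 7 fell of 29 tested (17 and 7 adjusted over the list alone), median log2 fold change 1.13, adjusted p = 0.004, and adjusted p = 0.564 with an estimated correlation. Members included Mmp2 (4.35 ± 0.18) and Lox (3.92 ± 0.27). Actin and SRF targets rose: 10 rose and 0 fell of 17 tested (10 and 0 adjusted over the list alone), median log2 fold change 0.48, adjusted p = 0.00207, and adjusted p = 0.599 with an estimated correlation. Members included Acta2 (2.80 ± 0.52) and Tagln (2.53 ± 0.31). Mitosis genes rose from their low level in spheroids: 16 rose and 0 fell of 24 tested (18 and 0 adjusted over the list alone), median log2 fold change 0.60, adjusted p = 1.36e-05, and adjusted p = 0.599 with an estimated correlation, with Ccnb1 at 3.90 ± 1.32. Among DNA replication genes, 10 rose and 1 fell of 27 tested (10 and 1 adjusted over the list alone), median log2 fold change 0.27, adjusted p = 0.0217, and adjusted p = 0.795 with an estimated correlation, a call lost without TGFB1 spheroid 3 (adjusted p = 0.0715). NOTCH pathway genes rose: 5 rose and 1 fell of 8 tested (7 and 1 adjusted over the list alone), median log2 fold change 1.04, adjusted p = 0.0126, and adjusted p = 0.271 with an estimated correlation. Members included Jag1 (2.35 ± 0.36) and Nrarp (2.04 ± 0.27). The NOTCH list call ended with filter at 5 (adjusted p = 0.0817). For mitochondrially encoded genes, 7 rose and 0 fell of 13 tested (11 and 0 adjusted over the list alone), median log2 fold change 0.58, adjusted p = 0.004, and adjusted p = 0.795 with an estimated correlation. Their call ended with quantile normalization (adjusted p = 0.4), where mt-Cytb turned from 0.69 to -0.15. The mt-Cytb call was also lost without untreated spheroid 2 (adjusted p = 0.0706), TGFB1 spheroid 2 (adjusted p = 0.0742) or TGFB1 spheroid 3 (adjusted p = 0.0542). They took 7.24%, 13.9% and 12.1% of the signal in the 3 TGFB1 spheroid libraries, against 7.80% to 8.68% in untreated spheroids.

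Ptgs2 rose from 732 ± 239 to 1395 ± 382 (adjusted p = 0.0326), a call lost without untreated spheroid 3 (adjusted p = 0.102), TGFB1 spheroid 2 (adjusted p = 0.127) or TGFB1 spheroid 3 (adjusted p = 0.065). Ly6a fell from 1.62 ± 0.427 to 0.297 ± 0.294 (adjusted p = 0.0165), a call lost without untreated spheroid 1 (adjusted p = 0.0614) or TGFB1 spheroid 2 (adjusted p = 0.0727). Brca1 did not pass (adjusted p = 0.337). The stemness list did not pass (median -0.07), with Cd44 (2.603 ± 0.47) higher and Aldh1a1 (-3.32 ± 0.62) lower. Medians, means and tests differed in sign for epithelial junction and keratin genes, EMT transcription factors, homologous recombination and damage checkpoint genes and NF-kB and inflammatory genes, none of which passed. In all, 4810 genes were called, 2544 higher and 2266 lower, 1519 by at least 2-fold, with no overlap in 43.9% of genes (10% by chance). The count was 3095 without TGFB1 spheroid 2 and 2787 in a fit of only the 6 libraries compared. With each library scaled to equal sums, the median of all genes moved to -0.16 and the calls to 1589 higher and 3751 lower. Among the 93 called genes that the rule named, 80 kept their call in each fit without 1 library and 76 in all other settings.

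Spheroids and monolayers were also compared under TGFB1. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 148 ± 22.1 to 61214 ± 18294 scaled TPM (log2 fold change 8.65 ± 0.41, adjusted p = 6.72e-08) and made up 4.09% to 7.92% of the signal of the TGFB1 spheroid libraries. Tgfb1 rose from 39.4 ± 0.766 to 797 ± 185 (log2 fold change 4.28 ± 0.13, adjusted p = 6.54e-09), Snai1 by 2.65 ± 0.31 log2 and Ptgs2 by 1.45 ± 0.31 log2, while Brca1 fell (-2.02 ± 0.15). Col1a1, which TGFB1 had raised in monolayers, was lower in TGFB1 spheroids (log2 fold change -4.22 ± 0.18, adjusted p = 3.43e-08). Ly6a did not pass (adjusted p = 0.744).

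Large increases were Chil1 (7.72 ± 0.16), Lcn2 (7.56 ± 0.56), Slco4a1 (7.43 ± 0.48) and Inhba (7.42 ± 0.63), and large decreases Fbln5 (-8.13 ± 0.31), Lrrn4 (-6.14 ± 0.28), Ackr4 (-6.04 ± 0.30), Krt7 (-5.94 ± 0.21) and Nell2 (-5.49 ± 0.19). Lcn2 encodes an iron-scavenging lipocalin, Inhba a subunit of activins, and Fbln5 an elastic fiber protein. All 3 spheroid libraries lay outside the range of the monolayers in each, which the rule for the largest changes required. Mitosis genes fell: 0 rose and 24 fell of 24 tested (0 and 24 adjusted over the list alone), median log2 fold change -3.25, adjusted p = 5.52e-19, and adjusted p = 0.181 with an estimated correlation. DNA replication genes fell: 0 rose and 26 fell of 27 tested (0 and 26 adjusted over the list alone), median log2 fold change -1.24, adjusted p = 1.57e-11, and adjusted p = 0.194 with an estimated correlation. Homologous recombination and checkpoint genes fell: 0 rose and 21 fell of 26 tested (0 and 21 adjusted over the list alone), median log2 fold change -0.83, adjusted p = 2.2e-07, and adjusted p = 0.194 with an estimated correlation. For actin and SRF targets, 1 rose and 15 fell of 17 tested (1 and 15 adjusted over the list alone), median log2 fold change -0.98, adjusted p = 1.34e-05, and adjusted p = 0.244 with an estimated correlation. Ovarian surface and mesothelial genes fell: 3 rose and 11 fell of 16 tested (3 and 12 adjusted over the list alone), median log2 fold change -2.52, adjusted p = 0.000914, and adjusted p = 0.244 with an estimated correlation. YAP and TEAD targets fell: 5 rose and 13 fell of 20 tested (5 and 13 adjusted over the list alone), median log2 fold change -0.996, adjusted p = 0.0107, and adjusted p = 0.181 with an estimated correlation. Members included Amotl2 (-4.16 ± 0.06) and Ajuba (-3.08 ± 0.11). ER chaperones fell: 2 rose and 13 fell of 18 tested (3 and 13 adjusted over the list alone), median log2 fold change -0.79, adjusted p = 0.00118, and adjusted p = 0.322 with an estimated correlation.

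NF-kB and inflammatory genes rose: 17 rose and 2 fell of 22 tested (19 and 2 adjusted over the list alone), median log2 fold change 1.58, adjusted p = 2.25e-05, and adjusted p = 0.244 with an estimated correlation. Members included Il1a (5.25 ± 0.64) and Il6 (3.10 ± 0.62). Hypoxia response genes rose: 12 rose and 0 fell of 19 tested (13 and 0 adjusted over the list alone), median log2 fold change 1.24, adjusted p = 2.25e-05, and adjusted p = 0.0998 with an estimated correlation. Members included Slc2a1 (3.21 ± 0.13) and Vegfa (2.40 ± 0.30). Immediate early genes rose: 10 rose and 0 fell of 16 tested (10 and 1 adjusted over the list alone), median log2 fold change 1.77, adjusted p = 0.00115, and adjusted p = 0.181 with an estimated correlation. Members included Egr2 (3.27 ± 0.26) and Junb (2.74 ± 0.13). Glycolysis genes rose: 8 rose and 0 fell of 17 tested (8 and 0 adjusted over the list alone), median log2 fold change 0.52, adjusted p = 0.00394, and adjusted p = 0.324 with an estimated correlation. In the interferon list, 1 rose and 11 fell of 22 tested (1 and 11 adjusted over the list alone), median log2 fold change -0.76, adjusted p = 0.00946, and adjusted p = 0.425 with an estimated correlation. For epithelial junction and keratin genes, 1 rose and 8 fell of 15 tested (1 and 8 adjusted over the list alone), median log2 fold change -0.68, adjusted p = 0.0135, and adjusted p = 0.194 with an estimated correlation, a call that ended with no filter on low values (adjusted p = 0.0793). The p53 targets fell: 2 rose and 10 fell of 24 tested (3 and 12 adjusted over the list alone), median log2 fold change -0.35, adjusted p = 0.0267, and adjusted p = 0.246 with an estimated correlation, a call lost without TGFB1 spheroid 1 (adjusted p = 0.0517). EMT factors did not pass: 4 rose and 2 fell of 8 tested (4 and 2 adjusted over the list alone), median log2 fold change 0.66, adjusted p = 0.195, and adjusted p = 0.322 with an estimated correlation. Those that rose included Twist1 (1.42 ± 0.21), Zeb2 (1.27 ± 0.14) and Zeb1 (1.17 ± 0.12). Medians, means and tests differed in sign for WNT target genes and oviductal epithelium markers, which did not pass.

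In all, 7009 genes were called, 3424 higher and 3585 lower, 2474 by at least 2-fold, with no overlap in 59.4% of genes (10% by chance). Of the 98 called genes that the rule named, 95 kept their call in each fit without 1 library and 95 in all other settings. As in untreated cells, culture and the origin of the libraries cannot be separated in this count. Nor can the timing of exposure, since spheroids had received TGFB1 before low-attachment culture. Scaled to equal sums, the median of all genes was -0.15 and 2423 genes were higher and 4898 lower.

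The interaction asks whether the TGFB1 effect differed between spheroids and monolayers. The effect on Tgfb1 itself was larger in spheroids by 2.86 ± 0.19 log2 (adjusted p = 8.29e-06). Effects on Chil1, a chitinase-like secreted protein gene, and Vsig8 differed by 6.64 ± 0.22 and 7.33 ± 0.46. Gdf6, a BMP family ligand gene, had a more negative response in spheroids (-4.16 ± 0.40, adjusted p = 0.000124). Snai1 and Ptgs2 did not pass (1.43 ± 0.44, adjusted p = 0.0513, and -1.22 ± 0.43, adjusted p = 0.0818), nor did Ly6a or Brca1 (adjusted p = 0.883 and 0.9).

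Of the lists, ER chaperones, which TGFB1 raised in monolayers, had a more negative response in spheroids: 0 rose and 7 fell of 18 tested (0 and 16 adjusted over the list alone), median log2 fold change -0.48, adjusted p = 9.5e-07, and adjusted p = 0.715 with an estimated correlation. Members included Hsp90b1 (-1.15 ± 0.16) and Creld2 (-0.85 ± 0.15). Cholesterol synthesis genes, which TGFB1 lowered in spheroids, also had a more negative response there: 0 rose and 2 fell of 22 tested (0 and 1 adjusted over the list alone), median log2 fold change -0.96, adjusted p = 0.00034, and adjusted p = 0.908 with an estimated correlation. For glycolysis genes, 0 rose and 4 fell of 17 tested (2 and 10 adjusted over the list alone), median log2 fold change -0.60, adjusted p = 0.00573, and adjusted p = 0.715 with an estimated correlation. Members included Pfkl (-1.52 ± 0.23) and Eno1 (-1.15 ± 0.19). Mitosis genes had a more positive response in spheroids: 6 rose and 0 fell of 24 tested (10 and 0 adjusted over the list alone), median log2 fold change 0.53, adjusted p = 7.32e-05, and adjusted p = 0.715 with an estimated correlation. Members included Cenpa (1.39 ± 0.19) and Ccnb2 (1.17 ± 0.28). For granulosa and theca markers, 0 rose and 2 fell of 6 tested (0 and 4 adjusted over the list alone), median log2 fold change -1.13, adjusted p = 0.0215, and adjusted p = 0.715 with an estimated correlation. Members included Nr5a1 (-1.04 ± 0.15). The granulosa and theca list call ended with filter at 5 (adjusted p = 0.056) or scaling to equal sums (adjusted p = 0.0699). The mesenchymal and matrix list showed no shift in 1 direction (median 0.00, adjusted p = 0.838). This test cannot detect members that move opposite ways, so it does not show that the matrix response was alike. Medians, means and tests differed in sign for EMT transcription factors, mesenchymal and matrix genes, actin and SRF target genes, stemness genes, immediate early genes, ovarian stroma and fibroblast markers and oviductal epithelium markers, none of which passed. In all, 2138 genes were called, 1178 with a higher and 960 with a lower response in spheroids. The 2 responses also come from libraries of different origin. Spheroids received TGFB1 before low-attachment culture, so the timing of exposure cannot be separated from culture either. The count was 1393 without untreated monolayer 3 and 1307 without TGFB1 spheroid 2, and 4385 with library quality weights. Scaled to equal sums, the median of all genes was -0.21 and the calls were 731 higher and 1914 lower. Among the 37 called genes that the rule named, 26 kept their call in each fit without 1 library and 25 in all other settings.

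The Snail comparison asks what overexpressing Snail changes in monolayer cells. Snai1 rose from 11.2 ± 2.15 to 207 ± 22.8 scaled TPM (log2 fold change 4.10 ± 0.13, adjusted p = 2.54e-05), and the change in other genes was small. Spint1, an epithelial protease inhibitor gene, fell from 90.0 ± 7.10 to 55.3 ± 1.46 (log2 fold change -0.69 ± 0.07, adjusted p = 0.00659), and Jup, which encodes the junction protein plakoglobin, from 147 ± 2.36 to 102 ± 6.82 (log2 fold change -0.53 ± 0.06, adjusted p = 0.00981). Cacna1g, a calcium channel gene, rose from 6.24 ± 1.08 to 16.5 ± 1.15 (log2 fold change 1.28 ± 0.12, adjusted p = 0.00659). Ptgs2 was 164 ± 11.8 and 207 ± 29.9 and did not pass (adjusted p = 0.209), nor did Tgfb1 or Brca1 (adjusted p = 0.646 and 0.776). Ly6a was below the filter at 0.356 ± 0.22 and 0.675 ± 0.179.

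Further increases were Col6a2 (1.75 ± 0.24), Dlk2 (1.22 ± 0.15), Col6a1 (1.19 ± 0.22) and Egfl7 (1.16 ± 0.13), and decreases Atp6v0e2 (-0.93 ± 0.09), Syt10 (-0.90 ± 0.08), Pnpla2 (-0.86 ± 0.06) and Tspan7 (-0.84 ± 0.06). The groups did not overlap in any of them, which the rule for the largest changes required. Epithelial junction and keratin genes fell: 0 rose and 4 fell of 12 tested (0 and 8 adjusted over the list alone), median log2 fold change -0.30, adjusted p = 2.22e-06, and adjusted p = 0.206 with an estimated correlation. Members included Ocln (-0.65 ± 0.10) and Krt18 (-0.57 ± 0.09). The epithelial list call ended with no filter on low values (adjusted p = 0.0633). Cholesterol synthesis genes fell: 0 rose and 2 fell of 23 tested (0 and 7 adjusted over the list alone), median log2 fold change -0.18, adjusted p = 2.3e-08, and adjusted p = 0.367 with an estimated correlation. For interferon response genes, 0 rose and 2 fell of 15 tested (0 and 3 adjusted over the list alone), median log2 fold change -0.35, adjusted p = 5.98e-06, and adjusted p = 0.341 with an estimated correlation. Members included Bst2 (-0.56 ± 0.07). The p53 targets rose: 1 rose and 0 fell of 24 tested (8 and 0 adjusted over the list alone), median log2 fold change 0.19, adjusted p = 9.25e-06, and adjusted p = 0.206 with an estimated correlation. Members included Phlda3 (0.52 ± 0.05). Glycolysis genes fell: 0 rose and 1 fell of 16 tested (0 and 5 adjusted over the list alone), median log2 fold change -0.13, adjusted p = 0.000358, and adjusted p = 0.367 with an estimated correlation. For DNA replication genes, 0 rose and 0 fell of 27 tested (0 and 0 adjusted over the list alone), median log2 fold change 0.11, adjusted p = 0.0121, and adjusted p = 0.754 with an estimated correlation, a call lost without vector control 1 (adjusted p = 0.0538), vector control 3 (adjusted p = 0.545) or Snail library 3 (adjusted p = 0.562). Mesenchymal and matrix genes did not pass (median 0.03, adjusted p = 0.105), nor did EMT factors (median 0.01).

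In all, 210 of 12240 genes were called, 70 higher and 140 lower, 18 by at least 2-fold, with no overlap in 20.6% of genes (10% by chance). The count was 64 without vector control 1, 66 without vector control 2, 52 without vector control 3, 58 without Snail library 1, 23 without Snail library 2 and 74 without Snail library 3, 54 with no filter and 16 with a replicate block. Of the 26 called genes that the rule named, 10 kept their call in each fit without 1 library and 7 in all other settings. Col6a2 lost its call without vector control 2 (adjusted p = 0.0641), vector control 3 (adjusted p = 0.0748) or Snail library 2 (adjusted p = 0.0814), Col6a1 without any 1 of the 6 libraries (adjusted p = 0.0513 to 0.153), Ocln without any 1 of the 6 libraries (adjusted p = 0.0608 to 0.113), Krt18 without vector control 1 (adjusted p = 0.0801), vector control 2 (adjusted p = 0.0679), vector control 3 (adjusted p = 0.0911), Snail library 1 (adjusted p = 0.104) or Snail library 2 (adjusted p = 0.125) and Bst2 without vector control 2 (adjusted p = 0.0507), vector control 3 (adjusted p = 0.0511), Snail library 1 (adjusted p = 0.0546) or Snail library 2 (adjusted p = 0.0539). Without Snail library 2, Jup, Dlk2, Egfl7 and Phlda3 missed the threshold (adjusted p = 0.0608, 0.0608, 0.0608 and 0.0539). With a replicate block, Spint1, Jup, Egfl7 and Phlda3 (each adjusted p = 0.0534) and Dlk2 (adjusted p = 0.0531) missed it. With no filter, Col6a2, Col6a1, Dlk2, Egfl7, Ocln, Krt18 and Bst2 missed it (adjusted p = 0.0991, 0.19, 0.0857, 0.073, 0.106, 0.133 and 0.0655). Medians, means and tests differed in sign for ovarian surface and mesothelial genes, YAP and TEAD target genes, WNT target genes and immediate early genes, none of which passed.

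**Figure D2:**
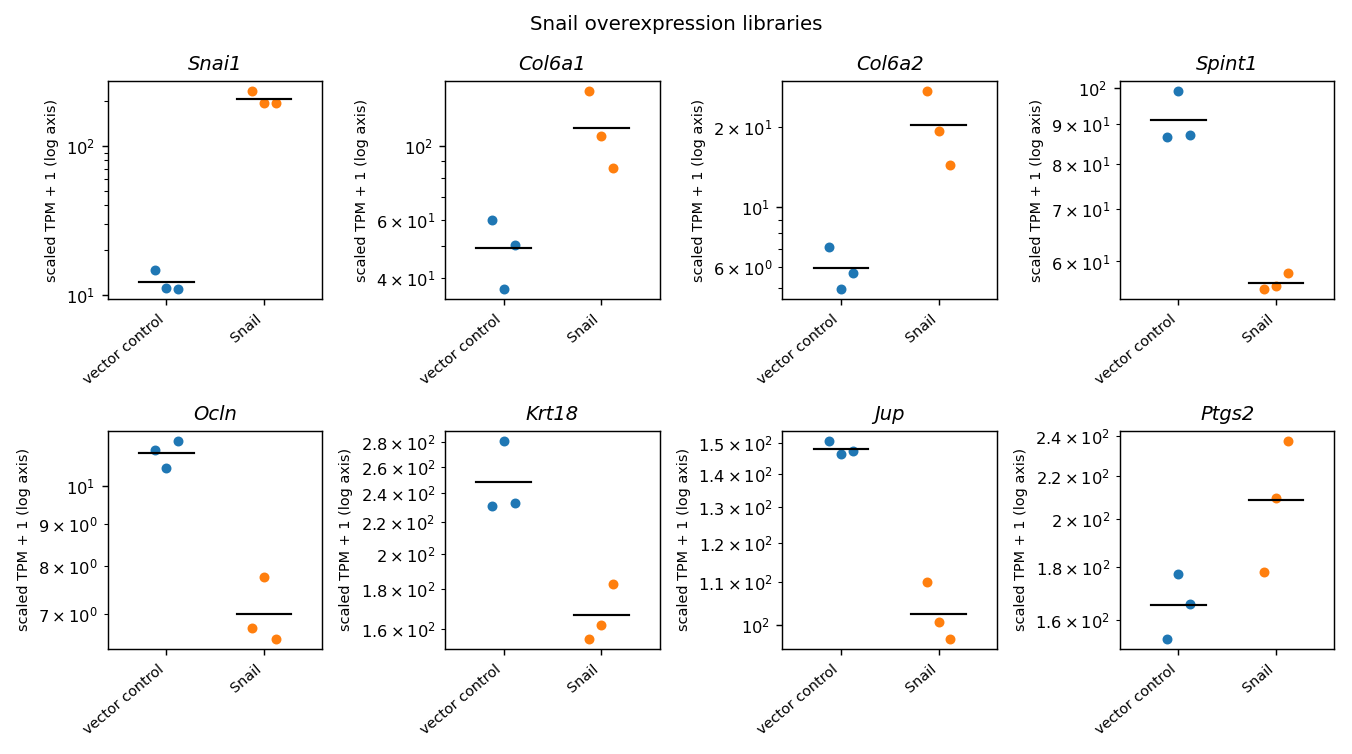
Scaled TPM + 1 on a log axis of 8 genes in the Snail table, with a point per library and a line at the mean of 3 libraries. Snai1 averages 207 in the Snail libraries and 11.2 in the vector controls, while Spint1, Ocln, Krt18 and Jup lie lower with Snail.

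The last comparison asks what deletion of BRCA1 changes. Igfbp5 rose from 7.26 ± 0.382 to 807 ± 417 scaled TPM (log2 fold change 6.50 ± 0.35, adjusted p = 0.000526), and Acta2, the smooth-muscle actin gene, fell from 988 ± 269 to 13.7 ± 5.14 (log2 fold change -6.10 ± 0.36, adjusted p = 0.000594). Ly6a rose from 0.796 ± 0.244 to 8.36 ± 2.69 (log2 fold change 2.35 ± 0.28, adjusted p = 0.00468), with each deletion library above each control. Ankrd1, a YAP target, fell from 93.1 ± 25.2 to 0.899 ± 0.445 (log2 fold change -5.63 ± 0.30, adjusted p = 0.000526). Brca1 itself was 4.27, 12.3 and 3.66 in the controls and 5.34, 11.1 and 4.09 in the deletion libraries (log2 fold change 0.09 ± 0.50, adjusted p = 0.904), and a level summed over the gene does not show whether the floxed part was removed. Snai1, Tgfb1 and Ptgs2 did not pass (adjusted p = 0.0708, 0.548 and 0.228).

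The control libraries stood apart from each other. Ribosomal protein genes took 20.2% and 21.1% of the signal in controls 1 and 3, against 8.33% to 10.4% in the other 4 libraries, and their sums were 1217651 and 1810667 against 796668 to 843146. For each gene, the log2 level of a library was also taken relative to the mean of all BRCA1 libraries. These deviations ran lower for longer transcripts in controls 1 and 3 (r = -0.308 and -0.324 across genes with log2 transcript length). Genes are not independent replicates. The other libraries had r = 0.211 to 0.26, but deviations from a shared mean balance out, so negative values in some libraries force positive ones in others. All 3 deletion libraries were on the side of control 2 in these measures, so the gap between controls overlaps with the comparison.

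With that limit, large increases besides Igfbp5 were Smoc2 (6.44 ± 0.47), Scg5 (5.95 ± 0.20), Greb1 (5.09 ± 0.25) and Sox6 (4.21 ± 0.23), and large decreases besides Acta2 and Ankrd1 were Rftn1 (-4.59 ± 0.28), Crip2 (-4.14 ± 0.38), Idh2 (-4.05 ± 0.42) and Fam184a (-3.81 ± 0.27). Smoc2 encodes a matricellular protein and Greb1 an estrogen-responsive factor. No deletion library overlapped the controls in any of these, which the rule for the largest changes required. EMT factors split: Twist1 (-2.66 ± 0.26) fell and Snai2 (2.01 ± 0.26) rose, and the list did not pass (median 0.16, adjusted p = 0.745). The Snai2 call was lost without deletion library 1 (adjusted p = 0.0737) or deletion library 2 (adjusted p = 0.0501). The stemness list did not pass either (median 0.49), and homologous recombination genes had a median of -0.22 (adjusted p = 0.301).

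DNA replication genes fell: 0 rose and 9 fell of 27 tested (0 and 22 adjusted over the list alone), median log2 fold change -1.56, adjusted p = 9.33e-10, and adjusted p = 0.66 with an estimated correlation, against a median of 0.17 for all genes. Mitosis genes fell: 0 rose and 2 fell of 24 tested (0 and 16 adjusted over the list alone), median log2 fold change -1.35, adjusted p = 4.43e-07, and adjusted p = 0.66 with an estimated correlation. For actin and SRF targets, 0 rose and 9 fell of 18 tested (0 and 12 adjusted over the list alone), median log2 fold change -1.32, adjusted p = 1.79e-07, and adjusted p = 0.169 with an estimated correlation. Members included Cnn1 (-2.12 ± 0.22) and Cnn2 (-2.10 ± 0.26). These 2 lost their calls without deletion library 1 (adjusted p = 0.0509 and 0.0622), and Cnn1 also with scaling to equal sums (adjusted p = 0.057). Cholesterol synthesis genes rose: 7 rose and 0 fell of 23 tested (12 and 0 adjusted over the list alone), median log2 fold change 1.03, adjusted p = 0.000909, and adjusted p = 0.66 with an estimated correlation. ER chaperones rose: 5 rose and 0 fell of 18 tested (9 and 0 adjusted over the list alone), median log2 fold change 0.999, adjusted p = 0.00528, and adjusted p = 0.665 with an estimated correlation, with Herpud1 at 3.08 ± 0.37, a list call lost without control 2 (adjusted p = 0.0998). Integrated stress response genes rose: 4 rose and 0 fell of 20 tested (6 and 0 adjusted over the list alone), median log2 fold change 0.87, adjusted p = 0.0272, and adjusted p = 0.66 with an estimated correlation. Members included Chac1 (2.00 ± 0.25). That list call was lost without control 2 (adjusted p = 0.283), and with library quality weights (adjusted p = 0.0653); Chac1 was lost without deletion library 1 (adjusted p = 0.064) or deletion library 3 (adjusted p = 0.0516). Herpud1 missed the threshold without controls 1 and 3 (adjusted p = 0.0604).

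In all, 1828 of 12775 genes were called, 1155 higher and 673 lower, 1601 by at least 2-fold, with no overlap in 44.9% of genes (10% by chance). The count was 57 without deletion library 1, 182 without deletion library 2, 162 without deletion library 3, 227 without control 1, 8295 without control 2 and 618 without control 3, and 620 without controls 1 and 3 together. Scaling to equal sums moved the median of all genes from 0.17 to 0.63, with 705 genes higher and 173 lower, and quantile normalization to -0.01, with 1194 higher and 1166 lower. The count was 1091 with no filter, 1050.0 with a filter at 5, 433 with a replicate block and 11536 with quality weights that did not converge. Of the 42 called genes that the rule named, 16 kept their call in each fit without 1 library and 20 in all other settings. Medians, means and tests differed in sign for epithelial junction and keratin genes, EMT transcription factors, TGF-beta and SMAD target genes, NOTCH pathway genes and NF-kB and inflammatory genes, none of which passed.

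**Figure D3:**
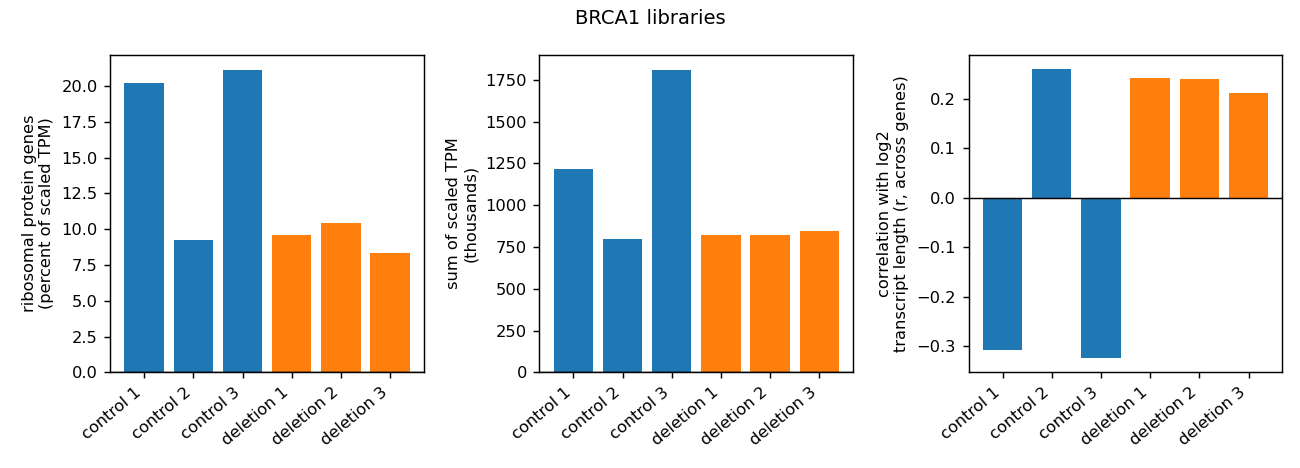
Bars per BRCA1 library: percent of the signal from ribosomal protein genes, sum of the signal, and a correlation across genes with log2 transcript length. The correlation uses the log2 level of a library minus the mean of all BRCA1 libraries. Controls 1 and 3 differ from control 2 and from the 3 deletion libraries in each panel.

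**Figure D4:**
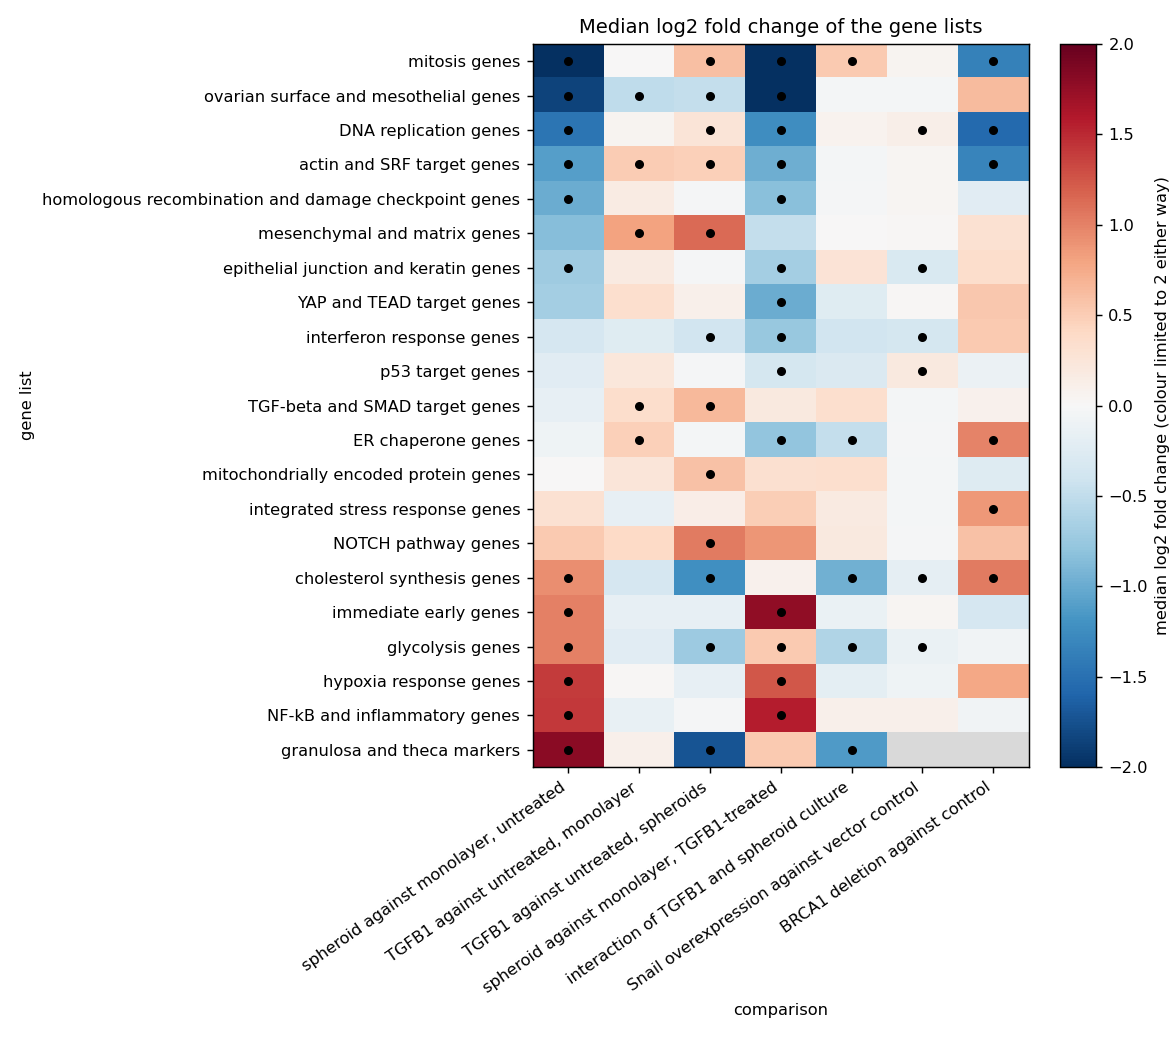
Median log2 fold change per gene list (lines) and comparison (columns), with the colour limited to 2 either way. Black points mark lists with an adjusted p under 0.05 at the preset correlation, none of which pass with an estimated correlation.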

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

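The TGFB1 response differed between spheroids and monolayers, by the interaction term of limma, for 2138 genes. The regrouping test of this part was chosen only after the result was seen. Of 100 draws that regroup the 12 libraries into 4 groups of 3, the real grouping included, 2 called as many genes, with 2424 as the highest of the others. Most draws mix monolayer and spheroid libraries, which widens the spread within groups whether or not the responses differ, so these draws leave open whether the grouping arose by chance. Responses higher in spheroids were Vsig8 (7.33 ± 0.46), Col5a3 (7.06 ± 0.39), Chil1 (6.64 ± 0.22), Serpinb2 (6.49 ± 1.67), Aqp1 (6.48 ± 0.77), S100a8 (6.39 ± 1.48) and Prss42 (6.36 ± 0.45) in log2. Responses lower in spheroids were Kctd14 (-5.32 ± 1.51), Clec2h (-4.63 ± 1.28), Akr1cl (-4.39 ± 1.27), Kirrel3 (-4.22 ± 0.65), Gdf6 (-4.16 ± 0.40), Cst12 (-4.15 ± 0.50), Spink4 (-4.11 ± 0.84) and Inpp5j (-3.92 ± 0.94). Chil1, Col5a3 and Vsig8 had adjusted p = 1.09e-07, 2.46e-06 and 5.35e-06. Serpinb2 lost its call without untreated monolayer 1 (adjusted p = 0.0555), untreated monolayer 2 (adjusted p = 0.051), untreated monolayer 3 (adjusted p = 0.0551), TGFB1 monolayer 2 (adjusted p = 0.0539), TGFB1 monolayer 3 (adjusted p = 0.0505) or TGFB1 spheroid 2 (adjusted p = 0.0537). Kctd14, Clec2h and Akr1cl lost theirs without any 1 library other than untreated spheroid 3 or TGFB1 spheroid 3 (adjusted p = 0.0574 to 0.0912).

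Some lists differed between the 2 responses: mitosis genes (median difference 0.53 log2), glycolysis genes (-0.60), cholesterol synthesis genes (-0.96), ER chaperones (-0.48) and granulosa and theca markers (-1.13). Their adjusted p with an estimated correlation was 0.715 to 0.908, so none passed that way. No explanation of these differences was tested. Among the untreated spheroids, library 3 resembled the other 2 least (r = 0.970 with each, while those 2 had r = 0.991 with each other). TGFB1 spheroid 1 had r = 0.969 and 0.965 with the other TGFB1 spheroids. The interaction was called for 1307 to 2658 genes without 1 library.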

How the results depend on the processing

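The added alternatives (scaling to equal sums, BRCA1 without controls 1 and 3, quality weights) and the splits were chosen only after the result was seen. The other settings were fixed beforehand. Of 123 counts recomputed, 92 stayed within 1.5 times. Of 8030 values of named genes, 7464 kept their side of the threshold, 549 lost and 16 gained a call and 1 reversed. Of 3392 list values the numbers were 3212, 79, 100 and 1. Direction was checked only where the main or the alternative fit called the gene or list, so uncalled values may have changed sign. The called genes of spheroid against monolayer culture, 7461 untreated and 7009 with TGFB1, stayed within 1.5 times in each alternative. The 2 reversals were mt-Cytb in TGFB1 spheroids, -0.15 with quantile normalization (adjusted p = 0.405), and the mitochondrially encoded list after BRCA1 deletion, mean 0.39 without controls 1 and 3 (adjusted p = 0.0265, not called otherwise at -0.23). With quality weights the counts were 6431 (TGFB1 in monolayers), 4385 (interaction) and 11536 (BRCA1, where the weights did not converge and ran from 0.0292 to 1820.3). With only the 6 libraries compared they were 3771 (TGFB1 in monolayers) and 2787 (TGFB1 in spheroids), against 2284 and 4810 in the joint fit. The joint fit takes 1 spread per gene over all 4 groups, and which culture had more TGFB1 calls depended on the fit. With no filter the counts were 54 (Snail) and 1091 (BRCA1). BRCA1 also gave 1050.0 with a filter at 5, 878 with equal sums and 620 without controls 1 and 3, where the lone control is assumed to vary like the other groups. Without 1 library the counts ran from 6386 to 7515 (untreated spheroids), 1220.0 to 1715 (TGFB1 in monolayers), 3095 to 4816 (TGFB1 in spheroids), 6019 to 6743 (TGFB1-treated spheroids against monolayers), 1307 to 2658 (interaction), 23 to 74 (Snail) and 57 to 8295 (BRCA1). Fewer libraries leave fewer degrees of freedom; for the other changes the cause was not tested. No list passed with an estimated correlation, a form of the test that also has few degrees of freedom.

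With a replicate block 16 (Snail) and 433 (BRCA1) genes were called. Libraries with the same number resembled each other in some pairs only (correlation of their deviations from the group means across genes 0.186, 0.137 and -0.016 for TGFB1 in monolayers, -0.248, 0.083 and -0.320 for TGFB1 in spheroids, 0.331, -0.015 and -0.078 for Snail, -0.053, -0.167 and -0.113 for BRCA1), so the numbers were not taken as pairs. The planned transcript-level alternative was not run because the tables hold genes. Each 3 against 3 comparison allows 10 splits, too few for a share under 0.05. The real split was the 1 with the most calls in each, 7461, 2284, 4810.0, 7009, 210.0 and 1828 genes against a highest other of 1, 2, 152, 2, 3 and 0 (untreated spheroids, TGFB1 in monolayers, TGFB1 in spheroids, TGFB1-treated spheroids, Snail, BRCA1). Every other split mixes the 2 groups, which widens the spread within groups. Few calls there follow from any difference between the groups, batch included, so the contrast gives no support of its own. Depth is unknown, so its limit on low genes could not be given.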

Other observations

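Overlaps of calls were counted for comparisons that share no library, beside the number expected if independent. TGFB1 in monolayers and in spheroids, from the same table, shared 572 against 232 higher in both, 375 against 176 lower in both, 99 against 207 higher then lower and 76 against 198 lower then higher. For untreated spheroids and BRCA1 deletion the numbers were 373 against 241 higher in both, 266 against 179 lower in both, 129 against 159 higher then lower and 173 against 270.5 lower then higher. TGFB1 in monolayers and Snail shared 26 against 6.51 higher in both, 27 against 12.03 lower in both, 15 against 13.02 higher then lower and 9 against 6.01 lower then higher. TGFB1 in monolayers and BRCA1 deletion shared 79 against 85.9 higher in both, 40 against 49.5 lower in both, 93 against 57.0 higher then lower and 103 against 74.6 lower then higher. Untreated spheroids and Snail shared 15 against 17.8 higher in both, 53 against 42.5 lower in both, 43 against 35.7 higher then lower and 23 against 21.2 lower then higher. For Snail and BRCA1 deletion they were 9 against 4.61 higher in both, 14 against 6.78 lower in both, 12 against 3.34 higher then lower and 17 against 9.35 lower then higher. In this pair every count exceeded the expected number, opposite directions included, so an excess alone need not be a shared response. The TGFB1 effects in monolayers and in spheroids also take 1 spread per gene from the joint fit. Of 24 tests of 200-gene sets, 9 passed at the preset correlation and 0 with an estimated correlation. The latter form also has few degrees of freedom, so its misses need not come from correlated genes. At the preset correlation the lowest adjusted p was 1.57e-13, for genes higher with TGFB1 in monolayers, which had a median of 0.57 log2 with TGFB1 in spheroids (adjusted p = 0.454 with an estimated correlation). With an estimated correlation the lowest was 0.187, for genes higher with Snail, which had a median of 0.25 log2 in TGFB1 monolayers (2.31e-05 at the preset correlation).

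Markers of other cell types gave these levels. Star was 293 ± 22.8 in untreated monolayers and Dcn, a stromal proteoglycan gene, 1332 ± 109. The highest leukocyte marker was Cd68 at 22.2 ± 4.01 in untreated monolayers and 47.4 ± 28.8 in untreated spheroids. Ddx4, a germ cell helicase gene, was 120.4 ± 45.2 in vector control and 125.7 ± 35.1 in Snail libraries, and 18.8 ± 7.62 in untreated monolayers of the other table, which was normalized separately. In the BRCA1 table it was 19.3 ± 7.65 in controls and 0.736 ± 0.23 in deletion libraries. Among the authors' tables, 555 Snail genes had a q-value under 0.05 and 203 of the 209 calls here that it lists were among them, all in the same direction. For BRCA1 the authors list 3380 genes among the 15437 in their table, 1499 higher and 1881 lower. The calls here, over the genes tested here, were 1155 higher and 673 lower. Over the 12596 genes in both, the authors called 3001 and 1805 were called here, with 1592 called in both and in the same direction. Over 8994 genes, their log2 coefficients minus those here had a median of -0.336. In the authors' monolayer and spheroid table, 12780 of 14491 genes had a q-value under 0.05 for the 3 terms together.

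The tests of the BRCA1 controls and of Cdh5 below were chosen only after the result was seen. BRCA1 controls 1 and 3 lay apart from control 2, with a root mean square log2 difference of 1.07 against at most 0.432 within the deletion group. Transcript length is a candidate cause, but with the length trend removed the difference was still 0.978 (highest within deletion 0.431), and the calls went from 1151 higher and 658 lower to 1101 higher and 1030 lower. Scaling alone left 0.944 after quantile normalization. A swapped label of control 2 would put it among the deletion libraries, yet it lay 0.726 from them, beyond the 0.432 among themselves. None of the 3 therefore accounts for the gap alone, and a difference in handling or batch, which the labels do not give, stays open.

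Cdh5, which encodes VE-cadherin, was 1.84 in untreated and 36.0 ± 14.0 scaled TPM in TGFB1 spheroids. Endothelial cells are a candidate source, but they would raise the other markers of the list as well, and the median increase of the other 8 was -0.0967 (range -0.820 to 1.64). Pecam1, chosen after its values were seen, went from 1.76 to 1.55. That argues against endothelial cells, and expression of Cdh5 in the cultured cells, as a hypothesis, stays open.

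Olfr1033, an olfactory receptor gene on chromosome 2, was chosen after its values were seen: it was the most abundant gene in all 3 vector control libraries, at 1.05% to 1.13% of the signal. It was also the most abundant gene in Snail library 2 (1.19%) and in BRCA1 deletion library 3 (2.33%). The test, set before its result was known, asked about shared sequence. Reads shared with other annotated transcripts might account for it. Of its 4288 sequences of 31 bases in the annotation, 10.5% occur in other genes, 397 of them in Olfr1032. That share neither requires nor excludes misassigned reads, since reads were not used here, and no biological explanation was tested.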
